A study of Mus musculus with 4 samples.

How the data were processed

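Total RNA of laser-captured mouse Paneth cells was extracted with the PicoPure kit and amplified and labelled with biotin with RiboAmp Plus, per the labels' protocols, and each of the 4 samples was hybridised to a 1-colour array. The labels assign 2 samples to the Atg16 hypomorph and 2 to the wildtype, and number the replicates. How many cells were captured, how the regions were chosen and which animals they came from are not given in the sources used here.

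The authors deposited 1 value per probe set and array, a linear intensity that ranged from below 1 to 20106 and was not on a log scale. The scaling between arrays, the background correction, the method that summarised probes and any detection calls are not given in the sources used here. Means trimmed by 2% at each end differed between arrays by a factor of at most 1.02, so the values were taken as already scaled and were not normalised again. All value columns were used.

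Probe sets were named from the platform annotation table given with the series. Of 45101 probe sets, 64 were control probe sets and were left out. Of the other 45037, 34945 carried 1 gene symbol, 932 several and 9160 none, and only those with 1 symbol were named. The gene ID of 34741 of them was found in a RefSeq gene table (assembly GRCm38.p6), and 0 symbols changed through it. The sources used here name no genome build, so that table served only for names, chromosomes and the order of genes, and no coordinates are given.

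Intensities were tested as log2(intensity + 32). Probe sets below the median mean log2 value (6.32) were left out, which kept 22519. A linear model with the group as its only term was fitted in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 residual and 7.81 prior degrees of freedom and Benjamini-Hochberg adjustment over probe sets. Calls are two-sided at an adjusted p under 0.05. A gene was represented by its brightest probe set, and 11577 genes had one that passed the filter. The residual spread rests on 2 arrays per group, and most of the precision comes from the spread shared across probe sets.

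Gene lists were tested with camera in limma at a preset correlation of 0.01 on the gene values, with Benjamini-Hochberg adjustment over the 35 of 38 lists that had 5 or more measured members. An estimated correlation per list and fry served as alternatives. With an estimated correlation camera tests on the 2 residual degrees of freedom, so a call lost there may reflect low power rather than correlated genes. Members were also adjusted over the list alone. PPAR signalling genes, adipokines and acute phase reactants are themes the study is known to have drawn from these samples. The comparison, the model, the lists, the rule for named genes and all alternatives except those named as added were chosen before the data were examined. The named genes were Atg16l1, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, and up to 4 members per list, called members by size first and otherwise those with the smallest unadjusted p. Other members of lists and other probe sets are named for context, and were chosen after their values were seen, as were the Y-linked and other single genes of the closing section. Genes of the families whose probes can cross-hybridise under that rule (defensin, haemoglobin, Saa, immunoglobulin, Mup and trypsin genes) are given as uncertain, and some other close paralogues are named as such beside their values.

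The alternatives were quantile normalisation, median centring, a pseudocount of 1 or of 4 times 32, other filters on dim probe sets, no intensity trend, a robust prior, the replicate number as a block, the mean of all probe sets of a gene, and each array left out in turn. In the last case the lone array of a group is assumed to vary like the other group. Added after seeing the data were lists without shared members, a list of genes largely restricted to fat cells, lists of glucocorticoid-responsive and core clock genes, and a test without chromosomes 2, X and Y. Positions of calls were compared with 10000 shuffles of the calls over the tested genes.

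The procedure was tested on simulated data for this comparison, with 200 of 22519 probe sets changed. It recovered 10.4% of those changed by a log2 difference of 0.5, 53.7% at 1 and 98.5% at 2, and 4 calls (3.57%) were false. With no change simulated it called 0 probe sets and 0 lists, and a list shifted by 0.4 was the 1 list called. Probe sets were drawn independently of each other with the fitted prior spread. The simulation therefore does not check list calls when genes are correlated or samples differ in other ways.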

Results

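The data were expression profiles of Paneth cells, the secretory cells at the base of the small intestinal crypt that release lysozyme and other antimicrobial proteins. The cells were cut from mouse tissue by laser capture, and 4 arrays were analysed, 2 from Atg16 hypomorph mice and 2 from wildtype mice of a mixed C57BL/6 and 129ola background. A hypomorph carries an allele with reduced function. Atg16l1 encodes a protein needed to form autophagosomes, the vesicles that deliver cell contents to the lysosome. Each array carried 45101 probe sets, whose median intensity lay between 47.4 and 49.6. Rank correlations across probe sets, which are not independent replicates, were 0.968 between the hypomorph arrays and 0.972 between the wildtype arrays, and 0.957 to 0.969 between arrays of different groups. All values below are deposited linear intensities given as mean ± SD (n = 2 arrays per group). Differences are hypomorph minus wildtype on the log2(intensity + 32) scale, which understates the change of dim genes. No label says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

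The comparison of hypomorph with wildtype asked how reduced Atg16l1 function alters transcription in Paneth cells. Among markers past the brightness filter, which a rise itself can lift a gene past, 12 of 16 fat cell markers and 14 of 25 enterocyte markers rose in the hypomorph samples. Both lists were called higher by camera in limma, but not with an estimated correlation (adjusted p = 0.25 for each). Scd1, a fatty acid desaturase, measured 5921 ± 287 against 683 ± 85 in wildtype, and the fat cell hormone Adipoq measured 678 ± 3.1 against 105 ± 5.81. Of 17 heat shock genes 5 fell, among them Hspa1b at 1442 ± 24.1 against 4231 ± 2.57, and of 16 enteroendocrine markers 5 fell. These lists too were called by camera but not with an estimated correlation (adjusted p = 0.26 and 0.54). The list of Paneth cell products was not called, although 3 of its 26 measured members rose, Reg3a, Ang and Reg3g, and the lysozyme gene Lyz1 was at 14829 ± 379 against 15751 ± 382. Xist, the RNA of the inactive X chromosome in female cells, was at 4462 ± 67.9 in hypomorph and 21.8 ± 5.36 in wildtype, so the groups also differed in a gene whose level depends on sex.

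Atg16l1 itself measured 966 and 995 on the hypomorph arrays and 1335 and 1183 on the wildtype arrays. Its log2 difference was -0.35 (SE 0.1), lower on both hypomorph arrays, but it did not pass the threshold (limma, adjusted p = 0.102). Where this probe set lies relative to the altered part of the gene is not given in the sources used here, so its level is a weak check of the labels. A second probe set of Atg16l1 was too dim to test.

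Of 22519 probe sets tested, limma called 836 at an adjusted p under 0.05, of which 459 were higher and 377 lower in hypomorph, and 135 and 84 of them differed by more than 2-fold. Taking the brightest probe set of each gene, 293 of 11577 genes were higher and 197 lower. At an unadjusted p under 0.05 there were 4625 probe sets, where 1126 are expected by chance. The count of lower calls depended on each array. It was 228 without hypomorph replicate 1, 178 without wildtype replicate 1 and 183 without wildtype replicate 2, and it rose to 942, with 706 higher, without hypomorph replicate 2.

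**Figure D1:**
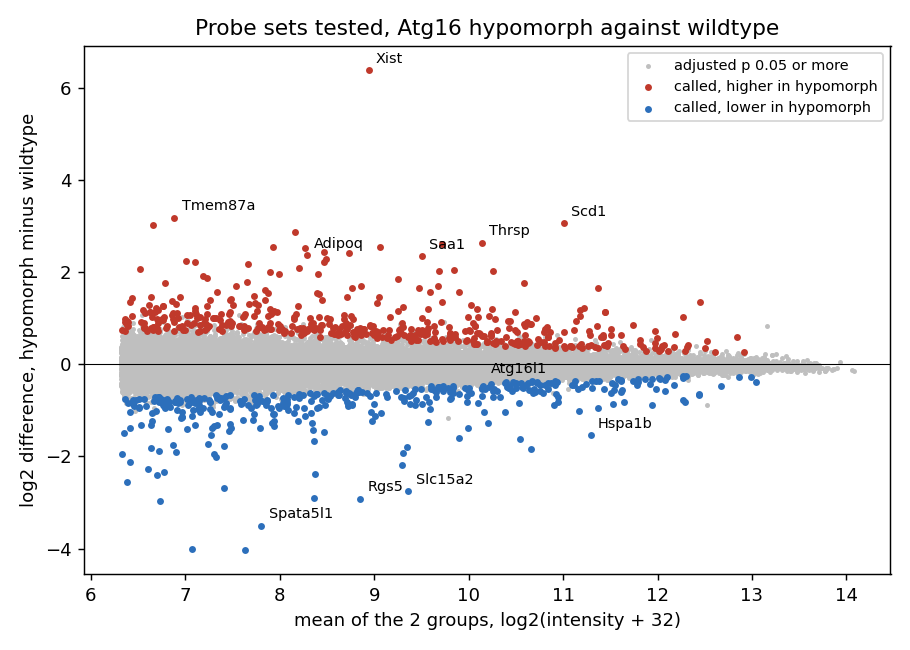
Each point is 1 of the 22519 probe sets tested, with the mean of the 2 groups on the log2(intensity + 32) scale on the horizontal axis and the log2 difference, hypomorph minus wildtype, on the vertical axis. The 459 called higher are red, the 377 called lower are blue, and Xist stands highest at 6.39.

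The 10 largest rises, led by Xist, included Scd1 (log2 difference 3.06, SE 0.1, adjusted p = 5.05e-07 in limma), the lipogenic regulator Thrsp (2.64), the cytochrome P450 Cyp2e1 (2.61), the fatty acid binding protein Fabp1 (2.41), Adipoq (2.37), the acute phase genes Saa1 (2.34) and Hp (2.28) and the lipid droplet protein gene Cidec (2.24). Tmem87a rose by 3.18, from 7.06 ± 0.346 to 325 ± 48.6. Probes of Saa1 can cross-hybridise with other Saa genes, so its identity is uncertain. Ranks of genes near the floor in a group, such as Ifi202b at 2.42 ± 2.01 in hypomorph, depend on the added 32. On the log2(intensity + 32) scale the largest fall of a named gene was that of Spata5l1, which dropped from 721 ± 4.07 to 34.4 ± 1.11 (log2 difference -3.50). Rgs5, a regulator of G protein signalling (-2.91), Smim10l1 (-2.91), the peptide transporter Slc15a2 (-2.75), Ifi202b (-2.56), BC064078 (-2.39), the Wnt antagonist Sfrp1 (-2.18), Dhrs1 (-2.01), the histidine-degrading enzyme Hal (-1.94) and Plet1 (-1.90) followed. These 20 genes were called without each array in turn wherever they passed the brightness filter, which Tmem87a, Ifi202b, BC064078 and Hal did not always do. Other probe sets of some of these genes gave much smaller differences, of 3.02 for Xist, 0.70 for Thrsp, -0.27 for Rgs5, -0.50 for Slc15a2 and -1.05 for BC064078. For Sfrp1 the other 2 gave -1.95, close to the named value, and 0.55, of opposite sign. Tmem87a and Spata5l1 both lie on chromosome 2, in a run of 100 neighbouring tested genes of which 19 were called.

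Fat cell markers had the largest mean rise of the 38 gene lists fixed in advance. Of 16 measured members 12 rose and 0 fell, with 13 rising when adjusted over the list alone, and the mean log2 difference was 1.39 (camera in limma, adjusted p = 2.65e-23, and adjusted p = 0.25 with an estimated correlation). Of 25 members on the array only these 16 passed the brightness filter, and a rise itself can lift a gene past it, as for Cidec, at 27.4 ± 14.8 in wildtype. Members left out near the floor include Retn (0.12), Lipe (-0.15) and Nnat (0.37). Beside Scd1, Thrsp, Adipoq and Cidec, the lipid droplet coat gene Plin4 was at 2439 ± 44.7 against 577 ± 69.6, and the hormone gene Lep at 256 ± 43.1 against 46.1 ± 6.31. Several members were already bright in wildtype, where Car3 read 3464 ± 53.2, Fabp4 3404 ± 112 and the lipoprotein lipase Lpl 1458 ± 43.1, and they read 8903 ± 266, 7040 ± 1039 and 4669 ± 9.07 in hypomorph. Dimmer probe sets of these 3 genes gave differences of 2.54 and 1.27 for Car3, 2.43 for Fabp4 and 2.21 for Lpl, against 1.35, 1.03 and 1.66 for the brightest. Pparg, the nuclear receptor of fat cell differentiation, had a log2 difference of -0.13 (adjusted p = 0.665 in limma). Beside these genes, 4 of 20 fibroblast and matrix markers and 0 of 11 endothelial markers rose, with list means of 0.21 and 0.23 (adjusted p = 0.26 and 0.54 with an estimated correlation in camera).

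Enterocyte markers rose as well. Of 25 measured members 14 rose and 0 fell, against 19 and 1 when adjusted over the list alone, and the mean was 0.69 (camera, adjusted p = 2.07e-20; adjusted p = 0.25 with an estimated correlation). Fabp1 was at 948 ± 79.7 against 153 ± 12.9. Apoa4, an apolipoprotein of chylomicrons, was at 1837 ± 33.4 against 421 ± 43.3, the lipid transfer protein gene Mttp at 1316 ± 56.7 against 498 ± 2.98 (with another probe set at a log2 difference of 0.58), and the brush border enzyme gene Alpi at 1595 ± 120 against 639 ± 65.7. Fabp2 at 8070 ± 336 against 7613 ± 67.5, and Fabp6 at 10237 ± 450 against 9862 ± 131, did not pass the test, and differences of probe sets this bright can be compressed.

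Lists of lipid metabolism and adipokines shared members with the fat cell list, and the PPAR list also with the enterocyte list. Among PPAR signalling genes 12 of 44 rose and 0 fell, against 16 and 2 when adjusted over the list alone, with a mean of 0.45 and a median of 0.10 (camera, adjusted p = 1.54e-08; adjusted p = 0.25 with an estimated correlation). The list was fixed in advance, but its theme is one the study is known to have drawn from these samples. Neither count is therefore independent evidence of its direction. Of the 12 that rose, 8 are also in the fat cell or enterocyte list, and without the members shared with those lists 4 of 32 rose, the mean was 0.13 and the median 0.036. The same holds for adipokines and their receptors, another theme drawn from these samples and not independent evidence. Of this list 5 of 13 rose and 0 fell, with the same counts when adjusted over the list alone (mean 0.70, camera adjusted p = 1.38e-05, and adjusted p = 0.26 with an estimated correlation). Of these 5, Adipoq, Lep and Rbp4 are fat cell markers too, and Socs3, an inhibitor of cytokine signalling, was at 2796 ± 242 against 806 ± 58.5. Without the members shared with the fat cell list, 2 of 10 rose and the mean was 0.32. In fatty acid and triglyceride synthesis 8 of 25 rose and 1 fell, against 10 and 2 when adjusted over the list alone (mean 0.46; camera, adjusted p = 4.25e-07; adjusted p = 0.26 with an estimated correlation). Dgat2, which completes triglyceride assembly, was at 3622 ± 198 against 1524 ± 36, and the acetyl-CoA carboxylase Acacb at 438 ± 2.88 against 227 ± 18. Without the members of this list shared with the fat cell or enterocyte list, 6 of 22 rose, 1 fell and the mean was 0.25. These settings without shared members were chosen after the data were seen, with unadjusted camera p-values of 0.0193 for the PPAR list, 0.0222 for adipokines and 4.76e-05 for synthesis, and p = 0.12, 0.14 and 0.075 with an estimated correlation. Leaving out shared members removes only genes that are on the fat cell and enterocyte lists. Other genes expressed in those cells may remain, so these settings cannot separate the themes from RNA of such cells. The fat cell list had its mean of 1.39 beside each of these lists. Fatty acid oxidation was not called (2 of 27 rose and 1 fell, and 3 and 3 when adjusted over the list alone; camera, adjusted p = 0.774), and Pdk4, a kinase that spares glucose, fell from 504 ± 32.7 to 166 ± 1.01. The 2 rises, of Acadl and Slc25a20, numbered 0 without hypomorph replicate 1 and without each wildtype replicate, and 1 without hypomorph replicate 2.

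**Figure D2:**
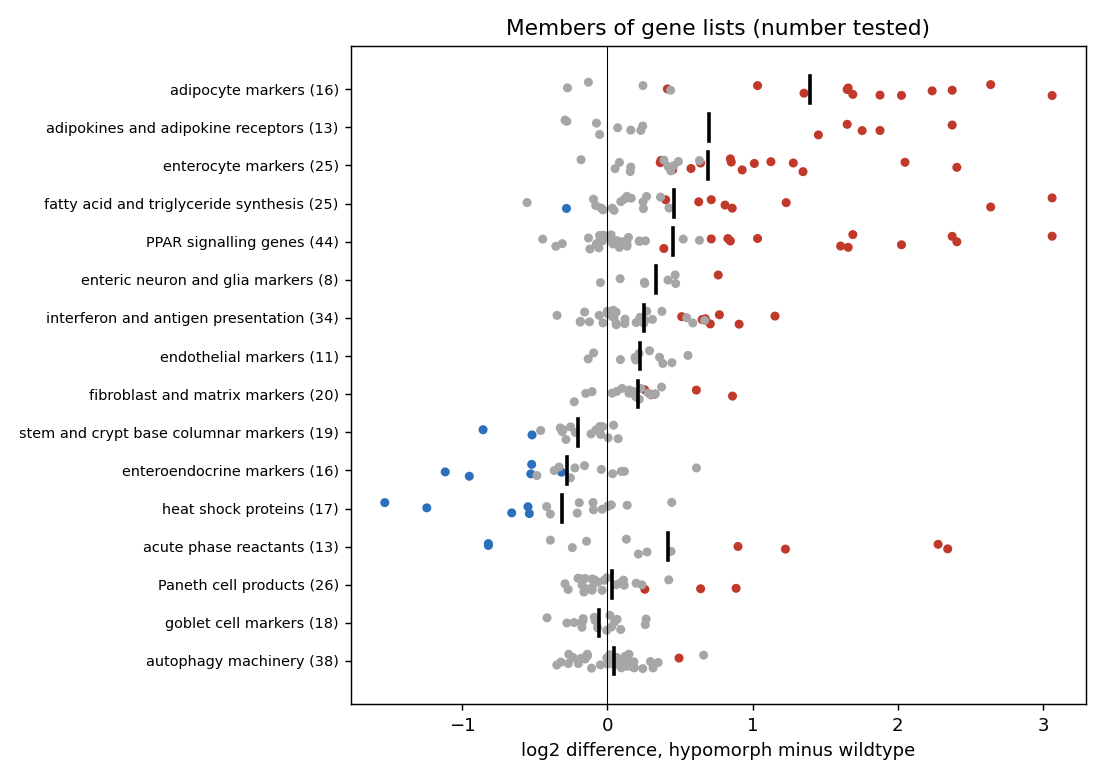
Each point is a measured gene of a list, placed by its log2 difference, hypomorph minus wildtype, on the horizontal axis, with the number of members tested beside the list's name. Red members were called higher, blue members lower and grey members not called, and black bars mark the list means, from 1.39 for fat cell markers to -0.31 for heat shock proteins among the 12 called lists, with 4 lists not called at the bottom.

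Acute phase reactants, the third list whose theme is known to be drawn from these samples and likewise not independent evidence, went both ways. Of 13 measured members 4 rose and 2 fell, against 5 and 4 when adjusted over the list alone, and the list was not called (mean 0.41; camera, adjusted p = 0.11). Saa1 was at 1603 ± 193 against 289 ± 13.7, the haemoglobin-binding Hp at 759 ± 23.2 against 131 ± 7.62, and F2 and Steap4 also rose, while Ttr fell from 1312 ± 61.4 to 730 ± 30.6 and the metallothionein Mt2 fell from 4208 ± 136 to 2371 ± 35.3. Interferon and antigen presentation genes rose in 7 of 34 cases and fell in 0, against 10 and 1 when adjusted over the list alone (mean 0.25; camera, adjusted p = 2.35e-05; adjusted p = 0.51 with an estimated correlation). Rsad2, an antiviral enzyme, was at 876 ± 103 against 376 ± 41.8, and Ifit1, Ifit3 and Ifi27l2a rose by 0.91, 0.77 and 0.71. The call of Ifit1 was lost without hypomorph replicate 2 and without wildtype replicate 2, and that of Ifit3 without replicate 1 of either group. The list also holds B2m, which rose by 0.51 and lies in the chromosome 2 run named above. Among T and NK cell markers, a list that was not called (2 of 14 rose and 0 fell, and 2 and 1 when adjusted over the list alone; camera, adjusted p = 0.608), the granzymes Gzmb and Gzma rose, to 533 ± 24.5 from 185 ± 50.1 and to 1603 ± 127 from 945 ± 9.2.

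The lists of connective tissue and nerve were called higher with smaller shifts. Fibroblast and matrix markers rose in 4 of 20 cases, and in 8 when adjusted over the list alone (mean 0.21; camera, adjusted p = 1.38e-05; adjusted p = 0.26 with an estimated correlation). They were led by the collagen gene Col1a1 at 637 ± 7.21 against 336 ± 4.24, followed by Mgp, Sparc and Col1a2. Of 11 endothelial markers 0 rose, and 1 when adjusted over the list alone (mean 0.23; camera, adjusted p = 0.00858; adjusted p = 0.54 with an estimated correlation). Of 8 enteric neuron and glia markers 1 rose by either adjustment, the neuropeptide gene Vip at 3763 ± 496 against 2195 ± 108 (list mean 0.33; camera, adjusted p = 0.00779; adjusted p = 0.49 with an estimated correlation). The fibroblast count was 2 without wildtype replicate 1, and without hypomorph replicate 2 there were 2 nerve markers that rose. Of the endothelial markers 1 rose without hypomorph replicate 2 and 1 without wildtype replicate 1. Among the matrix genes named, Col1a1 was called without each array in turn, and the other three were each lost without hypomorph replicate 2 and without 1 or more other arrays.

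Heat shock proteins fell in 5 of 17 cases and rose in 0, against 6 and 1 when adjusted over the list alone (mean -0.31; camera, adjusted p = 0.000101; adjusted p = 0.26 with an estimated correlation). The inducible chaperone gene Hspa1b fell by 1.53, Hspa1a fell from 744 ± 59.7 to 297 ± 40.6, Hsph1 fell from 6935 ± 7.6 to 4383 ± 108, and Hspb1 fell from 1329 ± 97.3 to 901 ± 95.2. Hspa1a and Hspa1b are near-identical copies, so their probes can cross-hybridise and the values are uncertain as to which gene they measure. Enteroendocrine markers fell in 5 of 16 cases and rose in 0, against 6 and 1 when adjusted over the list alone (mean -0.28; camera, adjusted p = 0.00136; adjusted p = 0.54 with an estimated correlation). The hormone gene Gip was at 59.6 ± 17.5 against 165 ± 9.21, Tac1 at 1864 ± 135 against 2703 ± 267 and Gcg, which encodes proglucagon, at 2079 ± 139 against 2995 ± 146, and Reg4 fell by 0.95. Stem and crypt base columnar markers fell in 2 of 19 cases, and in 5 when adjusted over the list alone (mean -0.20; camera, adjusted p = 0.00363; adjusted p = 0.31 with an estimated correlation). These were Msi1 at 164 ± 20.3 against 323 ± 27.9 and Cd44 at 826 ± 42.2 against 1197 ± 63.5. Without wildtype replicate 1 the enteroendocrine falls numbered 3 and the stem cell falls 0, and the stem cell falls numbered 1 without wildtype replicate 2 and 5 without hypomorph replicate 2. The calls of Tac1 and Msi1 were lost without wildtype replicate 1, that of Cd44 without each wildtype replicate, and that of Hspb1 without replicate 1 of either group. None of the 12 list calls was kept with an estimated correlation between genes. That setting tests on 2 residual degrees of freedom and has little power here, so the losses alone do not show correlated genes. For PPAR signalling genes the estimated correlation was -0.019, below the preset 0.01, yet the unadjusted camera p went from 1.32e-09 to 0.018. Among the 12 lists the estimates ranged from -0.045 for adipokines to 0.18 for enteroendocrine markers. They were 0.14 for endothelial, 0.13 for interferon and 0.11 for fat cell markers. For lists with such estimates the preset may be too low, and correlated genes may have made their camera p-values too small. The alternative fry, which asks whether a list's genes move on balance one way, called 8 of the 12. It did not call the enteroendocrine, interferon, endothelial and enteric neuron lists (fry in limma, adjusted p = 0.067, 0.076, 0.075 and 0.081), and called the acinar and hepatocyte lists, which camera did not.

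Paneth cell products were not called as a list. Of 26 measured members 3 rose and 0 fell, with the same counts when adjusted over the list alone (camera, adjusted p = 0.608), and the median of -0.05 differed in sign from the mean of 0.03 and from the test's upward direction. The lectin Reg3a was at 96 ± 4.6 against 38.1 ± 15.9, the ribonuclease Ang at 3394 ± 524 against 2154 ± 187 and Reg3g at 8417 ± 556 against 7024 ± 58.5. Members among the brightest on the arrays did not pass the test, including Lyz1 (log2 difference -0.09), Ang4 (-0.14), Mmp7 (-0.04) and Defa31 (-0.17), a defensin whose probes can cross-hybridise within its family. Probes of Ang and Ang4, and of Lyz1 and Lyz2, can also cross-hybridise with related genes, so these values are uncertain too. The highest value on each array lay between 15978.6 and 20106.1, and differences of probe sets this bright can be compressed, so their small differences do not exclude a change of these genes. Without wildtype replicate 1 the count of rises was 1, and without hypomorph replicate 2 there were 2 rises and 3 falls. The call of Reg3a was lost without replicate 1 of either group and that of Reg3g without each array but hypomorph replicate 1. Autophagy genes were not called either (1 of 38 rose, and 2 when adjusted over the list alone; camera, adjusted p = 0.283), the call being Atg4c at 1161 ± 17.3 against 816 ± 45, which was lost without hypomorph replicate 1 and without each wildtype replicate. In the unfolded protein response 2 of 37 rose by either adjustment (camera, adjusted p = 0.259). These were Chac1 at 1619 ± 201 against 522 ± 33.8, which lies in the chromosome 2 run, and Trib3 at 344 ± 8.2 against 178 ± 15.8, which was not called without wildtype replicate 2. The rises in this list numbered 4 without hypomorph replicate 2 and 1 without wildtype replicate 2.

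**Figure D3:**
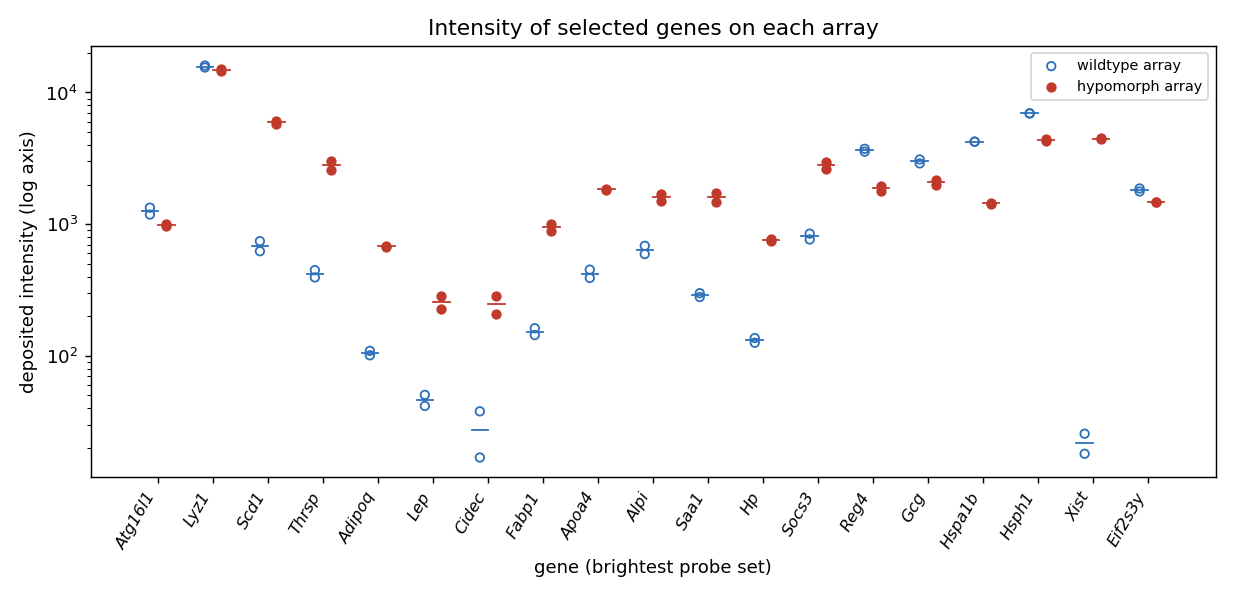
Each point is the deposited intensity of a gene's brightest probe set on 1 array, on a log axis, with open blue points for the 2 wildtype arrays and filled red points for the 2 hypomorph arrays, and short lines at the group means. Lyz1 reads near 15751 in wildtype and 14829 in hypomorph, while Scd1 reads 683 and 5921.

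The remaining lists were not called by camera. Goblet cell markers had 0 calls among 18 (mean -0.06), with Muc2 at 6355 ± 162 against 7194 ± 188. Tuft cell markers had 1 fall among 6, that of Rgs13 (-0.66), and proliferation genes 1 fall among 28, that of Kif11 (-0.54). Cholesterol synthesis had 0 calls among 19, the lysosome 1 rise among 31, that of Ctsd (0.50), and secretory granule genes 1 rise and 1 fall among 30, Syt1 (0.78) and Snap23 (-0.90). Other probe sets of Snap23 gave 0.02 and -0.08, that of Syt1 gave 0.03, and Snap23 is in the chromosome 2 run. Oxidative phosphorylation had 2 falls among 46, Cox7c (-0.81) and Sdhc (-0.37), and the oxidative stress list 2 rises among 23, Me1 (0.72) and Cat (0.28). Inflammatory genes had 2 rises and 1 fall among 24, in Cxcl1 (0.90), Ccl5 (0.67) and Ccl28 (-0.56). The other 2 probe sets of Ccl28, both dimmer, gave 0.25 and 0.36, so its direction is uncertain. Smooth muscle had 1 rise among 14, that of Pcp4 (0.45), and macrophage, dendritic and neutrophil markers 0 calls among 12. B and plasma cell markers had 1 fall among 13, that of the immunoglobulin gene Ighm (-1.27), whose probes can cross-hybridise. Pancreatic acinar genes had 1 rise and 1 fall among 7, Amy1 (1.40) and Sycn (-0.73, with another probe set at -0.04), and hepatocyte genes 1 rise and 1 fall among 6, Cyp2e1 and Ttr. Immediate early genes had 2 rises and 1 fall among 18, Socs3, Gadd45g (0.68) and Fos (-0.49). Cytosolic ribosomal proteins had 1 fall among 33, that of Rplp0 (-0.48), and the proteasome 0 calls among 31. These counts were made over all probe sets tested, and camera gave adjusted p-values from 0.0853 for ribosomal proteins to 0.926 for B and plasma cells. When adjusted over the list alone, the lysosome had 0 rises, secretory granule genes 1 rise and 2 falls, the oxidative stress list 2 and 1, inflammatory genes 2 and 2, hepatocyte genes 1 and 2 and immediate early genes 3 and 3, and the other lists of this paragraph had the counts above. Of the calls named here, those of Rgs13, Kif11, Ctsd, Me1, Cat, Pcp4 and Fos were lost without hypomorph replicate 1 and without each wildtype replicate, those of Syt1 and Sycn without hypomorph replicate 2 and each wildtype replicate, and that of Sdhc without each array in turn. Those of Snap23, Cox7c, Cxcl1 and Gadd45g were lost without 1 or 2 arrays, hypomorph replicate 1 for Gadd45g, wildtype replicate 1 for Cox7c, both for Snap23, and hypomorph replicate 1 and wildtype replicate 2 for Cxcl1. Without hypomorph replicate 1, cholesterol synthesis had 3 rises and macrophage, dendritic and neutrophil markers 1 rise. Without hypomorph replicate 2, falls numbered 1 each among goblet cell, macrophage and proteasome genes, 2 each among proliferation and hepatocyte genes, and 3 each among secretory granule and ribosomal protein genes. Mast cell, erythrocyte and sex-linked lists had 0, 1 and 4 measured members, too few for a list test. For fatty acid oxidation the median was 0.03 and the mean -0.03, for B and plasma cells 0.08 and -0.05, and for T and NK cells -0.07 and 0.06, while camera placed all 3 upward. The acinar list, with a median of -0.05 and a mean of 0.03, the secretory granule list, with -0.0021 and -0.02, and the oxidative stress list, with -0.0004 and 0.03, also had values of opposite sign to the upward direction of the test.

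RNA quality was read from probe sets along 2 control genes. The log2 difference between 3' and 5' probe sets of Gapdh was 5.03 and 5.17 in hypomorph and 5.09 and 5.17 in wildtype, and that of Actb was 4.04 and 4.17 against 4.53 and 4.34, lower on both hypomorph arrays by 0.33 on average. Y-linked genes gave signal on all 4 arrays. Eif2s3y read 1469 ± 5.59 in hypomorph and 1818 ± 66.7 in wildtype (limma, adjusted p = 0.093), and Kdm5d fell from 388 ± 23.3 to 235 ± 3.4, a call lost without hypomorph replicate 1 and without each wildtype replicate. Of the 82 named genes that were called, 33 had another tested probe set, and in 30 of these all the others had the same sign.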

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

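The setting without chromosomes 2, X and Y was chosen after the data were seen, and all others were planned. Of the 836 calls, 0 changed direction in any setting that tests probe sets, a weak check because the settings share the same arrays. Many calls were nevertheless lost in some settings. Of the 836, 280 were still called without a filter on dim probe sets and 323 without an intensity trend. By contrast, 773 were kept with median centring and 829 with a robust prior. Quantile normalisation, median centring, smaller and larger pseudocounts, a looser filter on dim probe sets and a robust prior gave between 409 and 531 higher and between 324 and 467 lower calls, and the added setting without chromosomes 2, X and Y gave 414 and 343. Without a filter on dim probe sets there were 183 higher and 120 lower calls, among 45037 probe sets tested. With the strictest filter on dim probe sets there were 244 lower calls, among 11260 probe sets. Without an intensity trend there were 192 higher and 131 lower calls, and with the mean of all probe sets of a gene 261 and 174, over genes. The cause was not tested for the trend. With each array left out in turn, higher calls ranged from 317 to 706 and lower calls from 178 to 942, the upper ends both coming without hypomorph replicate 2, and 48 of the 82 named calls held without each array. The labels share replicate numbers across groups, but no label says that a number marks a pair. Over 2 pairs the deviations correlated at 0.26. A probe set of the control spike BioB read higher on replicate 1 in each group, at 1316 against 764 in hypomorph and 942 against 671 in wildtype. No separate test of a batch shared by replicate number was run. A planned setting fitted the replicate number as a block, which leaves fewer residual degrees of freedom. With the replicate number as a block, 1489 probe sets were higher and 1717 lower, and the Atg16l1 difference of -0.35 passed the threshold (limma, adjusted p = 0.017, against 0.091 to 0.448 in the other settings). The cause was not tested. The number of lists called lay between 11 and 14 in all settings of the preset correlation, was 10 with fry (8 of the 12 called by camera, and the acinar and hepatocyte lists besides) and was 0 with an estimated correlation. The signs of named genes were kept except for Ccl28, at 0.016 with the mean of its probe sets, since the dimmer ones gave 0.25 and 0.36 against -0.56 for the brightest. Dim probe sets limit what can be seen, as 8 of 16 genes largely restricted to fat cells and the second Atg16l1 probe set lay below the brightness filter.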

Other observations

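The tests in this part were chosen after the results were seen, except that the bound for the PPAR list without shared members was set before its value was known, and its reading was narrowed afterwards. Several genes known to respond to glucocorticoids fell in hypomorph. In a list of such genes drawn up after some of these falls had been seen, which is therefore no test of the group, 7 of 17 measured members fell, 0 rose and the rest did not pass, 5 of the 17 being higher. Sgk1, a kinase that controls sodium transport, was at 1578 ± 41.7 against 3246 ± 237, the clock gene Per1 at 91.3 ± 13.8 against 202 ± 18.4, Zbtb16 at 552 ± 38.6 against 926 ± 55.4, Errfi1 at 998 ± 58.2 against 1503 ± 43.4 and Tsc22d3 at 2426 ± 72.3 against 3596 ± 311. Pdk4 and Mt2 were the other two. Fkbp5, a widely used marker of the response, was at 809 ± 21.8 against 1081 ± 11.8 and did not pass the test (limma, adjusted p = 0.0637). Of 15 core clock genes 1 fell and 0 rose, on brightest probe sets. Per2 had -0.63 on its brightest probe set (limma, adjusted p = 0.0607) and -0.71 on a dimmer one that was called (limma, adjusted p = 0.0473). Per3 had 0.08 on its brightest, while dimmer ones gave -0.58, -0.55 and -0.41 and were not called. Ppargc1a, a coactivator of mitochondrial gene expression, had a difference of -0.51 on its brightest probe set, which did not pass the test (limma, adjusted p = 0.0781). Of its other 4 tested probe sets 3 were called, at -0.98, -0.91 and -0.83, and 1 was not, at -0.29.

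Xist was high on both hypomorph arrays and near the floor on both wildtype arrays. Hypomorph samples from females alone are argued against by Eif2s3y, a Y-linked gene whose hypomorph to wildtype intensity ratio was 0.81. Samples holding cells of both sexes in the hypomorph, and of males in wildtype, may account for it, since 3 of 3 Y-linked genes tested were lower in hypomorph, with ratios of 0.6 for Kdm5d and 0.66 for Uty. Whether sex is the source of autosomal calls cannot be told apart from genotype, because both differ between the same arrays. Of 342 X-linked genes 3.8% were called, against 4.22% of 11188 autosomal genes (Fisher's exact test, two-sided, p = 0.89). Those shares do not decide what lies behind the autosomal calls. An effect of genotype stays open and untested.

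Fat cell markers (12 of 16 rose), lipid synthesis genes (8 of 25) and enterocyte markers (14 of 25) rose in hypomorph. A lower share of Paneth cells that raised all other cell types alike is argued against by enterocyte and enteroendocrine means that differed by 0.971 (SE 0.16 over genes, which are not replicates). Captures that gained some cell types and lost others are not covered by that comparison and stay open. List means were 0.69 for enterocyte, 0.21 for fibroblast, 0.23 for endothelial and 0.33 for enteric neuron markers. They were -0.20 for stem cell, -0.28 for enteroendocrine, -0.21 for tuft and -0.06 for goblet cell markers. Whether shared members account for the PPAR list stays open. Without them 4 of 32 rose, with a mean of 0.13 and a median of 0.036, and the camera p of 0.0193 met the bound set in advance. That bound does not decide, because the study drew the theme of the list from these samples and the camera p was 0.12 with an estimated correlation. RNA of fat tissue, which laser capture is meant to exclude, cannot be told apart from a change of transcription in the captured cells, since the 16 genes largely restricted to fat cells had a median difference of 0.44, which does not decide. The 8 past the brightness filter had a median of 2.05 and 7 of them rose, led in level by Plin4 at 2439 ± 44.7, Adipoq at 678 ± 3.1 and Slc36a2 at 573 ± 32.4. A rise itself lifts a gene past that filter, however, and the 8 below it, at -0.15 to 0.50, lie near the floor and exclude nothing. The median of all 16 rests on such dim genes, whose differences the added 32 shrinks. Mrap, for example, read 17.2 ± 4.26 against 2.66 ± 2.18, a difference of 0.50, while Lipe was lower in hypomorph at -0.15.

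Called genes lay next to each other on chromosomes. There were 49 neighbouring pairs, against a mean of 20.4 and a highest of 40 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). This argues against calls placed independently of their neighbours. Shared regulation of neighbouring genes was not tested, since the shuffles break it too. When genes of similar name were left out, there were 36 pairs against a mean of 19.8. A chromosome segment inherited from different strains of the mixed background may account for part of this, since the densest run of 100 tested genes, on chromosome 2, held 19 calls, where the densest run of each shuffle held 11.5 on average and 20 at most (permutation p = 0.0002), 11 higher and 8 lower, from Slc5a12 to AA467197 and including Tmem87a, Spata5l1, Vps39 and Chac1. DNA carried along with the altered Atg16l1 locus cannot be told apart from chance placement, as 6 of 81 genes around it were called where 3.41 are expected, more than at 84% of positions. Sequence differences under a probe and differences in expression are both open, and an effect of genotype on these genes was not tested.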
